A study of Clostridium acetobutylicum with 10 samples.

How the data were processed

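The series tested a protocol for an Agilent array of 60-base probes for Clostridium acetobutylicum, an anaerobic bacterium that makes butanol and acetone. Per the labels, 1 RNA pool of strain ATCC 824 carried Cy3 and 1 RNA pool of strain M5 carried Cy5 on all 10 arrays, and the direction of every ratio below rests on these dyes. Cultures grew in clostridial growth medium with glucose, and total RNA was copied with random hexamers and coupled to the dyes through aminoallyl groups, per the labels' protocols. Each pool mixed samples of the exponential phase, at optical densities of 1.09, 1.8, 2.6 and 2.0 for ATCC 824 and of 4.20, 3.20, 2.40, 1.36 and 0.868 for M5. The labels of the M5 channel also list 0.454, which the series text leaves out, so the makeup of that pool is known only to that extent. The labels give 4 amounts of labelled material (0.5, 1.0, 3.0 and 5.0 µg) and pairs of photomultiplier (PMT) settings, and the file headers show that each amount was 1 slide scanned 2 to 4 times. The slide with 5.0 µg was scanned on an earlier day than the other 3, so amount, slide and scan day cannot be told apart. The rescans show that the first PMT number belongs to Cy3 and the second to Cy5.

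Each deposited scanner file holds 22575 spots, of which 21495 are probes for 3916 genes, 162 are negative controls and 918 are positive controls. The submitters' processing notes name Agilent Feature Extraction 8.5, and the file headers give 8.5.1.1. The mean and background intensity of each channel are unnormalized pixel values, per the file headers. The processed intensity of each channel was background-subtracted and dye-normalized by the scanner software with a linear and LOWESS step, per the file headers. The deposited log10 ratio is that of processed Cy5 over processed Cy3, and it equalled the log10 of these signals within 0.001 for 98.9% of spots. The deposited series table holds values on a natural log scale, Cy5 over Cy3, as its slope on the log2 ratio of bright spots was 0.698 against 0.693 for a natural log. Its column medians were −0.0251 and −0.0026 for replicates 1 and 2 at 0.5 µg, −0.0534 and −0.0527 at 1.0 µg, and −0.0254 and −0.0451 at 3.0 µg. At 5.0 µg the medians of replicates 1 to 4 were 0.0185, −0.0305, −0.0723 and −0.0378. The columns therefore lie near 0 without being centred exactly on it, and the normalization behind them is not given in the sources used here. Saturated spots (0 with a value) and spots with an outlier mark (0 with a value) were blank there.

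The main values were computed from the mean intensities and median local backgrounds with limma 3.58.1 in R 4.3.3, with data.table at version 1.17.8. Background was corrected with normexp and an offset of 50, and log2 ratios were normalized by loess within each array with control spots and outlier spots at weight 0. Outlier spots were then left out, and saturated spots were kept. A gene's ratio on an array was the median over its probes. Scans of a slide were averaged first, and the reported log2 ratio is the mean over the 4 amounts with its SD. Positive values mean more signal from M5. This SD measures differences between slides of the same pools and leaves out the spread between scans of a slide. P-values here measure technical spread only, because there was 1 biological sample per strain. No test between the strains was made. The number of arrays limits the precision, and with no dye swap the ratio of strains includes any dye effect. The pools also differed in the densities sampled, so strain and growth stage were not separable.

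A gene was measured where at least 1 probe was well above background in at least 1 channel at every amount. Chromosomal genes were counted where they were at least 2-fold apart with a value and one sign on all 10 arrays, so a gene without a value on any array was not counted. A gene with no probe well above background in a channel on any array would have had a bound in place of a ratio, taken from channel levels after loess and Aquantile. Only CAC1409 and, in the M5 channel, CAP0023 met that condition, both unmeasured, and no bound is printed. Levels from the same step gave the plot of ratio against level. Gene names and descriptions are those of the array design and can be old, and no genome was used here, so no coordinates are given.

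The text names 72 genes by a rule. It takes every measured member of the lists for pSOL1 solvent genes, acid formation, butyryl-CoA formation, butanol dehydrogenases, and pyruvate and hydrogen. It adds the 12 highest and 12 lowest measured chromosomal genes with a value and one sign on all 10 arrays and one sign over all their probes. It also takes the 2 members of each other list with the largest ratios in size. There were 23 gene lists, including the whole pSOL1 megaplasmid. The other lists covered glycolysis, heat shock and chaperones, sporulation, motility and chemotaxis, ribosomal proteins, F1F0 ATP synthase, aminoacyl-tRNA synthetases, purine, pyrimidine, histidine, tryptophan, branched-chain amino acid and fatty acid biosynthesis, PTS sugar uptake, the cellulosome, iron uptake, and phage and transposon genes. Before values were read, 4 loci with other annotated products were left out of the tryptophan and fatty acid lists. A list's median was placed among 10000 random lists of the same size, matched on signal in 10 bins, and stood apart where it lay outside the 2.5 to 97.5 percentiles. The groups, lists, naming rule and comparisons of the report, with their tests and alternatives, were fixed before the data were examined, except for 2 additions to the iron uptake list, 1 gene left out of each of 2 lists, lists moved along the chromosome, and the tests that the closing parts name as chosen later.

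The trend of the ratio with the amount was fitted with limma on the 4 arrays at PMT 80 and 40 against log2 amount, with eBayes and Benjamini-Hochberg adjustment at 0.05. That fit had 2 residual degrees of freedom, or 4.8 after moderation. Shares of probes well above background or saturated came from the scanner software's marks, with 95% Wilson intervals that cover counting error only. Rescan ratios used probes with a net signal over 200 and no saturated pixel. Alternatives covered background correction, normalization, probe summary, arrays used, saturated spots, dim probes, thresholds, the series table and leaving out each array or amount. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

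The ratio, trend and random-list steps were tested on simulated data. In simulated arrays of 3916 genes, true log2 ratios of −3 and 3 came back as −2.81 and 2.79 at brighter probes and as −1.90 and 2.20 at dimmer probes. True ratios of −1 and 1 came back as −0.94 and 0.92 at brighter probes and as −0.74 and 0.67 at dimmer ones. All 50 genes at −3 and all 50 at 3 were at least 2-fold apart, against 5 of 50 at −1, 0 of 50 at 1 and 0 of 3716 without a difference, so ratios are drawn toward 0 and counts at the 2-fold limit leave out genes close to it. In a simulated trend over 3864 genes, 64 of 100 genes with a slope of 0.2 per doubling and 93 of 100 with 0.5 were called, with 4 false calls. Its errors were independent between genes, with no effect shared by the genes of a slide, so these counts do not give the power or error of the real fit. Of 200 simulated lists of 20 genes without a shift, 14 (7.0%) stood apart, against 196 (98.0%) with a shift of 1. Simulated genes were independent, whereas ratios of neighbouring loci in the data correlated at r = 0.612, so these shares do not describe lists of neighbouring loci.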

Results

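RNA from 2 strains of Clostridium acetobutylicum was compared on 10 scans of 4 two-colour arrays. ATCC 824 is the type strain, and M5 is a mutant derived from it that is known to have lost the megaplasmid pSOL1, which carries the genes for solvent formation. The same pair of exponential-phase RNA pools was loaded at 0.5, 1.0, 3.0 and 5.0 µg, with 2 scans of each of the 3 smaller amounts and 4 scans of the largest. Median net signal at PMT 80 and 40 went from 180.2 in Cy3 and 329.1 in Cy5 at 0.5 µg to 773.8 and 1544.2 at 5.0 µg. Ratios below are log2 of M5 over ATCC 824, as mean ± SD over the 4 amounts (n = 4 slides of the same pools). With 1 pool per strain there was no biological replicate and no test of the strains.

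Genes of pSOL1 were lower in M5. Acetoacetate decarboxylase, the last enzyme of acetone formation (adc, CAP0165), stood at −9.67 ± 0.52, with at least 1 probe saturated in ATCC 824 on 8 arrays and all probes on 3. It was −9.35 without saturated spots, −11.32 with the scanner software's signals and −11.98 in the series table. The aldehyde dehydrogenase CAP0162, named adhe1 in the array design, was at −8.43 ± 0.31. The CoA-transferase subunits that take up acids during solvent formation stood at −6.99 ± 0.59 (ctfA, CAP0163) and −6.51 ± 0.39 (ctfB, CAP0164). The aldehyde-alcohol dehydrogenase CAP0035, which the array design describes as ADHE1, was at −6.82 ± 0.63 and pyruvate decarboxylase (pdc, CAP0025) at −5.90 ± 0.42. Probes of pdc ran from −6.99 to −4.20, a spread that the SD over amounts does not cover. All 6 solvent genes were at least 2-fold lower, with a median of −6.91, or −10.32 with the software's signals, −9.92 in the series table and −8.02 with an offset of 16. Over the 178 pSOL1 genes the median was −1.51 ± 0.29, with 172 genes lower in M5 on every array that gave a value and 0 higher on every such array. At least 2-fold lower, with a value and one sign on all 10 arrays, were 108 genes, and 46 were at least 8-fold lower. The 45 genes brightest in ATCC 824 had a median of −5.04, and the 45 dimmest had −0.48. The ratio also holds the ATCC 824 level used for this split, and the log2 M5 level was nearly flat over it (slope 0.02). The gap therefore does not show a smaller loss at dim genes. For the 176 measured genes the median of −1.53 lay at percentile 0 of matched random lists, a place given in advance by the loss of pSOL1.

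Median M5 signal at pSOL1 probes lay closer to that of negative controls than to that of chromosomal probes. In the M5 channel at PMT 80 and 40, median net signal at pSOL1 probes was 9.5 at 0.5 µg and 110.1 at 5.0 µg, beside 7.9 and 58.3 at negative controls and 370.3 and 1717.9 at chromosomal probes. At least 1 probe was well above background in M5 on 6 arrays for ctfA, on 8 for CAP0035 and ctfB, and on all 10 for adc, CAP0162 and pdc. The pSOL1 median was −3.87 with the scanner software's signals, −3.03 in the series table and −2.10 with an offset of 16.

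**Figure D1:**
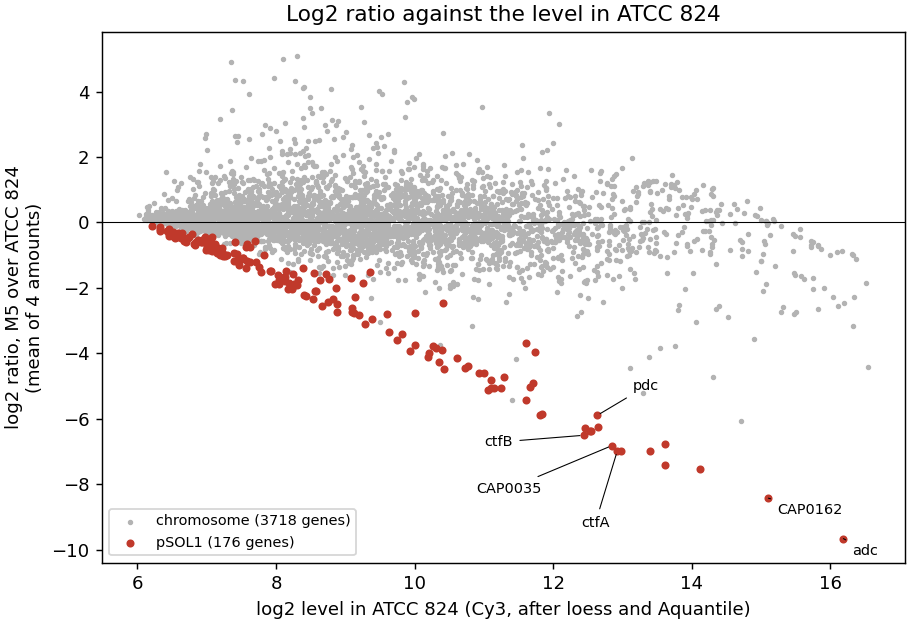
Log2 ratio of M5 over ATCC 824 (mean of 4 amounts) against log2 level in ATCC 824, with 3718 measured chromosomal genes in grey, 176 measured pSOL1 genes in red and the 6 solvent genes named. The pSOL1 genes run downward from about 0 at dim probes to −9.67 at adc. The ratio also holds the ATCC 824 level, so a nearly flat M5 level gives such a run.

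On the chromosome, 403 of 3718 measured genes were at least 2-fold higher in M5 and 246 at least 2-fold higher in ATCC 824, together 17.5%. The software's signals gave 617 and 330 genes, 947 in all. At least 8-fold differences were seen for 32 and 16 genes. With median centring in place of loess the counts were 578 and 174, so that 76.9% of the genes counted were higher in M5 against 62.1% with loess. The median SD over amounts was 0.095, with a 95th percentile of 0.253, and the median SD between probes of a gene was 0.121. Chromosomal genes had a median ratio of 0.03 and an SD of 0.879 between them, which holds differences between the 2 pools that 1 pool per strain cannot part from biological variation.

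The highest ratios belonged to leucine, isoleucine and valine synthesis and to purine synthesis. Acetolactate synthase (ilvB, CAC3169) was at 5.08 ± 0.30, the isopropylmalate dehydratase subunits at 5.00 ± 0.25 (leuC, CAC3173) and 4.89 ± 0.26 (leuD, CAC3172), isopropylmalate synthase (leuA, CAC3174) at 4.31 ± 0.15 and isopropylmalate dehydrogenase (leuB, CAC3171) at 4.09 ± 0.93. The dihydroxy-acid dehydratases stood at 4.34 ± 0.32 (ilvD, CAC3170) and 4.10 ± 0.16 (ilvD, CAC3604). All 6 measured members of the branched-chain list were at least 2-fold higher in M5, with a median of 4.62 ± 0.26 (percentile 100), or 5.60 with the software's signals, 5.51 in the series table and 5.08 with an offset of 16. Of 9 purine genes 8 were, with a median of 3.83 ± 0.09 (percentile 100), led by purM (CAC1393) at 4.32 ± 0.16, purN (CAC1394) at 4.30 ± 0.17 and purF (CAC1392), the first step of the pathway, at 4.02 ± 0.23. Of 11 pyrimidine genes 7 were, with a median of 2.29 ± 0.04 (percentile 100), including carbamoylphosphate synthase (carB, CAC2644) at 3.19 ± 0.29 and dihydroorotate dehydrogenase (pyrD, CAC2650) at 2.96 ± 0.23. A gluconate permease (gntP, CAC2835) at 4.40 ± 0.28 and a predicted peptidase (CAC0659) at 4.15 ± 0.25 completed the 12 highest genes.

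Histidine synthesis went the other way, with a median of −0.62 ± 0.14 over 9 genes (percentile 0.16, but 5.22 among lists that keep its spacing of loci, where it did not stand apart) and 1 gene at least 2-fold lower, hisZ (CAC0935) at −1.19 ± 0.12, which the array design describes as a histidyl-tRNA synthetase and which is also in that list, followed by hisD (CAC0937) at −0.83 ± 0.11. With the software's signals and in the series table, the histidine median was −0.78 and −0.84 and hisZ was at −1.86 and −1.94. The tryptophan list did not stand apart (median 0.24 ± 0.03 over 5 genes, percentile 85.7), and its median was 0.60 with the software's signals and 0.01 with median centring. In that list trpD (CAC3161) stood at −0.56 ± 0.13 and trpF (CAC3159) at 0.29 ± 0.09. Of 61 genes in the ribosomal protein list 54 were above 0, with 31 at least 2-fold higher, 1 at least 2-fold lower and a median of 1.01 ± 0.08 (percentile 100), or 1.55 with median centring. On single arrays that median ran from 0.39 to 1.24, a spread that its SD does not cover. The list also holds a ribonuclease and a penicillin tolerance protein, each fused to a ribosomal protein S1 domain. Ribosomal protein S10 (rpsJ, CAC3134) stood at 1.67 ± 0.34, and a protein similar to ribosomal proteins (CAC1801) at 1.96 ± 0.15. Aminoacyl-tRNA synthetases had a median of 0.29 ± 0.10 (percentile 92.0), with 5 of 27 at least 2-fold higher and 3 at least 2-fold lower, and seryl-tRNA synthetase (serS, CAC0017) at 3.49 ± 0.13 and methionyl-tRNA synthetase (metS, CAC2991) at 2.54 ± 0.05 were the farthest from 0.

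Among the lowest chromosomal genes was a cluster for ferrichrome uptake, a route for iron, while 2 other genes for ferrichrome-binding proteins were higher in M5, CAC1988 at 1.74 ± 0.25 and CAC2441 at 1.44 ± 0.22, both named after their values were seen. A ferrichrome permease (CAC0788) stood at −5.22 ± 0.31, its binding protein fhuD (CAC0790) at −4.74 ± 0.18, the permease fhuB (CAC0789) at −4.19 ± 0.35 and the ATP-binding protein fhuC (CAC0791) at −4.12 ± 0.20, beside the neighbouring locus CAC0787 at −4.46 ± 0.16. With the software's signals and in the series table, CAC0788 was at −5.655 and −5.80 and fhuB at −4.965 and −5.05, beyond their SDs. The iron uptake list had a median of −0.39 ± 0.07 (percentile 3.25), with 7 of its 16 genes at least 2-fold lower and 5 at least 2-fold higher in M5, and its place among random lists turned on its members and their summary. It stood apart with the mean of the probes (median −0.49), and with feoB (CAC1031, −2.55 ± 0.57) added (−0.75 ± 0.10, percentile 0.03). It did not with all 7 iron uptake genes that its wording had left out (0.26 ± 0.07, percentile 89.2), of which feoB and CAC0447 were at least 2-fold lower and CAC1989, CAC1990, CAC2443, CAC2877 and CAC2878 at least 2-fold higher. These 2 additions were chosen after the data were seen. The SD over amounts does not cover the spread between probes of a gene, which ran from −5.62 to −3.51 for CAC0788. The hypothetical protein CAC0588 stood at −6.06 ± 0.25, with probes from −6.26 to −4.20. Its neighbour, the electron carrier flavodoxin (CAC0587), was at −4.42 ± 1.096 with all probes saturated in ATCC 824 on 9 arrays. Its value of −6.04 without saturated spots came from 1 array. A dicarboxylate translocator (CAC1590) was at −5.42 ± 0.82, with M5 signal well above background on 6 arrays, and at −8.56 with the software's signals, −8.17 in the series table and −6.45 with an offset of 16. The 4 others were arbA (CAC1471) at −3.83 ± 0.06, CAC1470 at −3.77 ± 0.21, the lipoprotein CAC1593 at −3.75 ± 0.20 (−5.45 with the software's signals and in the series table), and lactate dehydrogenase (CAC0267), which reduces pyruvate to lactate, at −3.57 ± 0.18. Probes of CAC1593 ran from −4.26 to −2.35.

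Genes of the central route to acids differed by less than 2-fold. Phosphotransacetylase (pta, CAC1742) stood at −0.27 ± 0.06, acetate kinase (askA, CAC1743) at 0.18 ± 0.11, butyrate kinase (buk, CAC3075) at −0.34 ± 0.18 and phosphate butyryltransferase (ptb, CAC3076) at −0.74 ± 0.16, or −0.55 without saturated spots. The acid formation list had a median of −0.30 ± 0.12 (percentile 27.9), which was 0.19 with median centring, where pta and buk were also above 0. Genes from acetyl-CoA to butyryl-CoA lay at −0.45 ± 0.04 (hbd, CAC2708), −0.73 ± 0.16 (etfA, CAC2709), −0.03 ± 0.21 (etfB, CAC2710), −0.41 ± 0.11 (bcd, CAC2711), −0.57 ± 0.25 (crt, CAC2712) and −0.55 ± 0.26 (acetyl-CoA acetyltransferase, CAC2873). All M5 probes were saturated on 5 arrays for etfA, on 3 each for hbd and CAC2873 and on 1 each for the others. Without saturated spots etfA was at −0.53 (from 3 arrays), hbd at −0.28, CAC2873 at −0.34 and etfB at 0.01. Their median of −0.50 ± 0.13 (percentile 12.3) was −0.345 without saturated spots and 0.09 with median centring, where hbd, etfB, bcd and CAC2873 were above 0. Butanol dehydrogenase A (bdhA, CAC3299) was at −1.44 ± 0.08, while butanol dehydrogenase B (bdhB, CAC3298) was at −0.26 ± 0.10, or 0.27 with median centring, and the median of both was −0.85 ± 0.09 (percentile 13.2). The hydrogenase hydA (CAC0028), which releases hydrogen, was higher in M5 at 1.55 ± 0.08. Pyruvate:ferredoxin oxidoreductase (CAC2229) was at 0.67 ± 0.71, with all probes saturated in M5 on 6 arrays, and at 1.33 without saturated spots, from 4 arrays. With lactate dehydrogenase these formed a list of 3 with a median of 0.67 ± 0.63 (percentile 82.3), which stood apart once saturated spots were left out. Glycolysis genes were lower in M5, with 4 of 10 at least 2-fold lower, 10 of 10 below 0 and a median of −0.92 ± 0.25 (percentile 0.26), or −0.38 with median centring. Enolase (eno, CAC0713) stood at −2.47 ± 0.47, with ATCC 824 saturated at all probes on 3 arrays, and phosphoglycerate mutase (pgm, CAC0712) at −1.70 ± 0.26.

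The motility and chemotaxis list had a median of −0.18 ± 0.06 over 93 genes (percentile 0.04, or 2.38 among lists that keep its spacing, close to the limit of 2.5), or −0.31 with the software's signals and −0.29 with an offset of 16, with 67 of them below 0, 26 above, 15 at least 2-fold lower and 1 at least 2-fold higher. Flagellin (CAC1634) stood at −2.85 ± 0.22 and hag (CAC2203) at −1.85 ± 0.70, or −2.45 from 5 arrays without saturated spots, with at least 1 probe saturated on 9 arrays and all probes in ATCC 824 on 5. Phage and transposon genes had a median of −0.73 ± 0.03 over 37 genes (percentile 0), or −0.43 with median centring, 16 of them at least 2-fold lower and 0 at least 2-fold higher, with CAC1886 at −2.02 ± 0.06 and CAC1888 at −1.63 ± 0.13. Sugar uptake by the phosphotransferase system had a median of −0.24 ± 0.08 over 30 genes (percentile 0.01, but 3.51 among lists that keep its spacing, where it did not stand apart), or −0.46 with median centring and with the software's signals, 2 at least 2-fold higher and 3 at least 2-fold lower, including enzyme I (CAC3087) at 1.56 ± 0.02 and the cellobiose component licB (CAC0384) at −1.46 ± 0.06.

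Sporulation genes did not stand apart, with a median of 0.01 ± 0.05 over 81 genes (percentile 38.9) that was −0.14 with median centring, −0.04 with pSOL1 probes at weight 0 in loess and −0.02 in the series table. In that list 4 genes were at least 2-fold higher and 3 at least 2-fold lower, and the forespore sigma factor F (CAC2306) stood at 1.79 ± 0.10 and its inhibitor spoIIAB (CAC2307) at 1.69 ± 0.07. Heat shock genes had a median of 0.26 ± 0.06 over 12 genes (percentile 79.2), or 0.87 with median centring and 0.44 without saturated spots, with the regulator hrcA (CAC1280) at 1.16 ± 0.13 and the chaperone grpE (CAC1281) at 0.94 ± 0.12. On single arrays the heat shock median ran from −0.08 to 0.72, a spread that its SD does not cover. The ATP synthase list had a median of 0.42 ± 0.07 over 8 genes (percentile 85.1), or 0.90 with median centring, with atpF (CAC2869) at 0.82 ± 0.29 and atpH (CAC2868) at 0.81 ± 0.02. Fatty acid synthesis had a median of −0.19 ± 0.07 over 10 genes (percentile 28.5), which was 0.19 with median centring, with fabH (CAC3578) at −0.82 ± 0.13 and fabF (CAC3573) at −0.51 ± 0.19. Cellulosome genes, which encode enzymes of plant wall breakdown, had a median of 0.26 ± 0.04 over 10 genes (percentile 95.2), or 0.05 with median centring and 0.63 with the software's signals, with the endoglucanases CAC0912 at 0.52 ± 0.21 and CAC0911 at 0.46 ± 0.10. Of the 23 lists, 11 stood apart from matched random lists of single genes. These hold the pSOL1 megaplasmid and its solvent genes, whose place was given in advance because M5 is known to lack pSOL1. Members of a list often lie at neighbouring loci, whose ratios correlated at r = 0.612, so each list was also moved to 3718 places along the chromosome with its spacing kept, a test chosen after the data were seen and not matched on signal. Then 9 of the 11 stood apart, again with the pSOL1 lists among them, while histidine synthesis (percentile 5.22) and sugar uptake (3.51) did not and iron uptake (1.36) did.

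**Figure D2:**
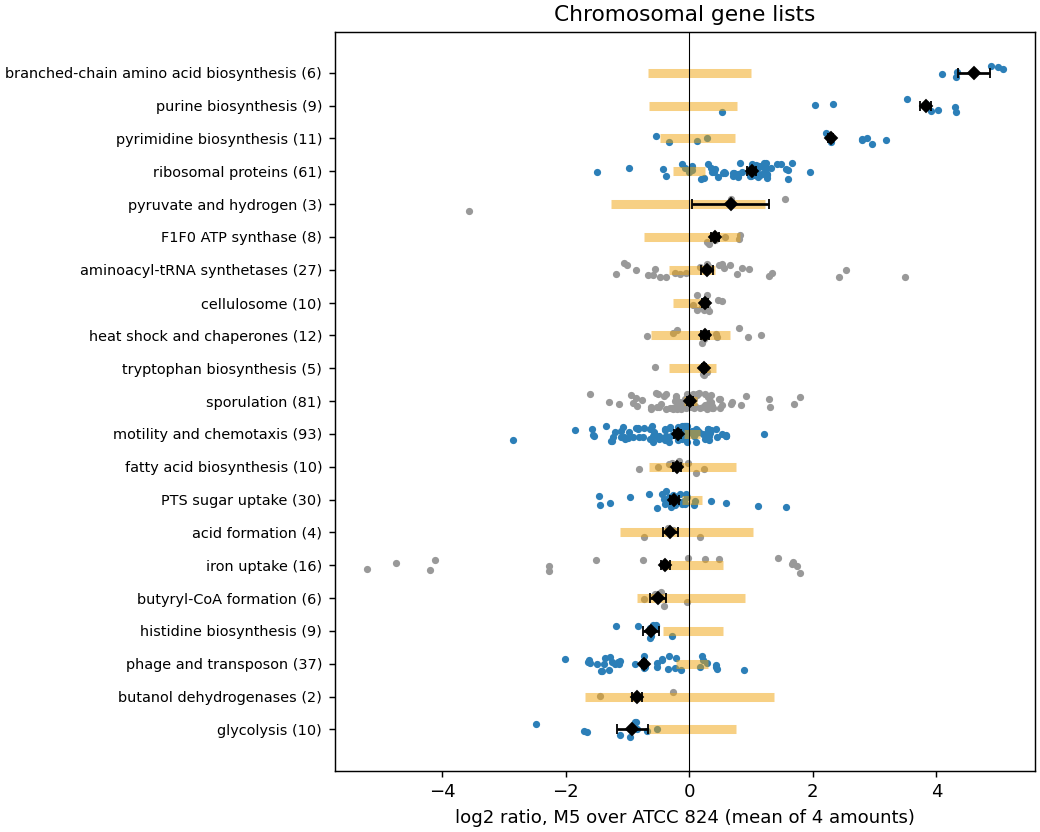
Log2 ratio of M5 over ATCC 824 (mean of 4 amounts) of each measured gene (points, blue where the list stood apart) in 21 chromosomal lists, with the median and its SD over amounts (black diamonds), the 2.5 to 97.5 percentile range of random lists (orange bars) and the number of genes in brackets. Branched-chain and purine synthesis lie at 4.62 and 3.83, and glycolysis at −0.92, or −0.38 with median centring.

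The amount loaded was compared at PMT 80 and 40. Probes well above background in Cy3, the ATCC 824 channel, made up 95.1% (95% Wilson interval 94.8 to 95.4) at 0.5 µg, 97.2% (97.0 to 97.4) at 1.0 µg, 98.4% (98.2 to 98.5) at 3.0 µg and 99.0% (98.8 to 99.1) at 5.0 µg. In Cy5, the M5 channel, they made up 93.5% (93.1 to 93.8), 95.8% (95.5 to 96.0), 97.2% (97.0 to 97.4) and 98.6% (98.4 to 98.7) in the same order. Of the pSOL1 probes, 24.2% were well above background in the M5 channel at 0.5 µg and 79.1% at 5.0 µg. Each setting was 1 array, so there was no replicate error for these shares.

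Saturation was compared between PMT settings on one slide. At 5.0 µg, 6.50% of probes were saturated in the M5 channel at PMT 100, 2.79% at 40, and 0.0651% and 0.0744% in the 2 scans at 10. In the ATCC 824 channel 0.600% were saturated at PMT 100, 0.395% and 0.386% at 80, and 0.181% at 60. Moving Cy5 from 40 to 20 took saturation in M5 from 1.32% to 0.228% at 1.0 µg, from 1.68% to 0.642% at 3.0 µg and from 0.340% to 0.0744% at 0.5 µg. ATCC 824 saturation at PMT 80 and at the lower Cy3 setting of 60 was 0.0930% and 0.0140% at 0.5 µg and 0.368% and 0.186% at 3.0 µg, and the 2 scans at 80 of the 1.0 µg slide gave 0.279% and 0.251%. Rescanning at an unchanged PMT gave signals lower by 2.08% (Cy3, 1.0 µg), 2.49% (Cy3, 5.0 µg) and 3.01% (Cy5, 5.0 µg). Ratios of chromosomal genes correlated across genes, which are not independent replicates, at r of 0.960 to 0.999 for 9 pairs of scans of one slide and 0.916 to 0.994 for 36 pairs on different slides.

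**Figure D3:**
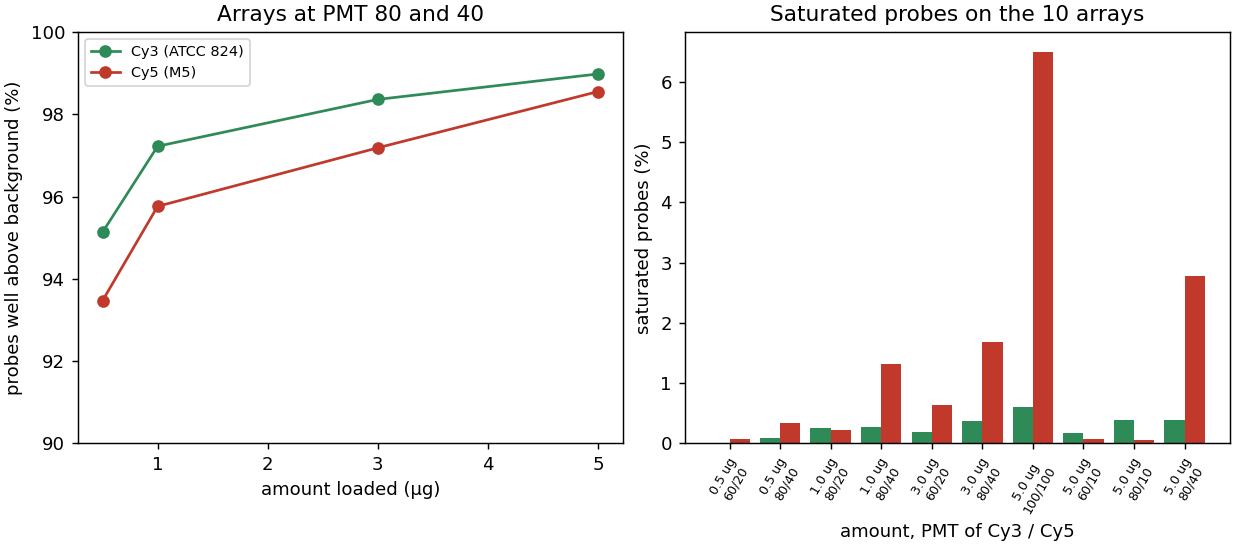
Left, percent of 21495 probes well above background against amount in µg on the 4 arrays at PMT 80 and 40, on an axis that does not start at 0. Right, percent of probes saturated on the 10 arrays by amount and PMT, with Cy3 (ATCC 824) in green and Cy5 (M5) in red, the highest bar being 6.50% for Cy5 at 5.0 µg and PMT 100.

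The dependence of the strain ratio on the amount was fitted for 3864 genes. The median slope of pSOL1 genes was −0.16 per doubling of the amount, against 0.01 for chromosomal genes and 0.07 for chromosomal genes with a saturated probe. With limma, 0 genes had a trend at an adjusted p of 0.05, the lowest adjusted p being 0.064, while 982 genes (25.4%) had an unadjusted p under 0.05 where chance gives 5%. Counts were 20 with median centring, 3 with the software's signals, and 1962 with all 10 arrays and PMT covariates, a fit that counts rescans of one slide as independent. Leaving out the 3.0 µg array gave 116 genes and leaving out the 1.0 µg array 11, against 0 without the 0.5 µg array and 0 without the 5.0 µg array, which was alone in its scan day.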

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

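The tests of carried-over RNA, of a common floor, of the offset, of saturated pSOL1 probes, and of all 3 explanations for small p values were chosen after the results were seen, as was the look at probes between slides. That of probe binding was set before its result was seen.

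For the 4 scans at 5.0 µg, 28 measures (list medians and shares of probes among them) were searched for a scan far from the other 3, and 2 had one, where chance gives about 1 in 20. Aminoacyl-tRNA synthetases had a median log2 ratio of 0.25 at PMT 80 and 40 (0.254) against 0.359 to 0.368 in the other 3 scans. Purine synthesis had 3.05 (3.052) at PMT 100 and 100 against 3.79 to 3.88. That scan had 6.50% of probes saturated in the M5 channel. Without saturated spots the purine median over the 4 amounts was 3.885, against 3.825 with them, and saturation was not tested as the cause for this scan. Outside the gene probes, 6 of 10 kinds of E1A control probe were above the 95th percentile of negative controls in both channels on all 10 arrays, with log2 Cy5 over Cy3 from −0.96 to 0.09 over the 10 kinds. Whether matching RNA was added, and at what ratio, is not given in the sources used here.

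M5 is known to lack pSOL1, yet its channel held signal at pSOL1 probes. ATCC 824 RNA carried over into the M5 pool is argued against as the whole source, because the slope of log2 M5 level on log2 ATCC 824 level over 178 genes was 0.02, and adc in M5 was at 0.123% of its ATCC 824 level. These levels include the offset, so a share below that of adc stays open. Whether binding particular to each probe contributes was not decided by the test set for it. The share of variance between genes in Cy5 was 0.392 of that in Cy3 in the median over arrays. It was 0.285 to 0.316 at 0.5 and 1.0 µg, but 0.507 to 0.533 on the 4 scans at 5.0 µg, above the limit of 0.5 set for this explanation. A common floor would lower this share as well, so the test cannot part the 2 explanations. Deviations of probes from their gene mean correlated between slides at 0.650 to 0.756 in Cy5 and at 0.698 to 0.920 in Cy3, so that measure does not single out M5. A floor common to all probes is argued against as the whole source on the 5.0 µg slide, where 52.3% to 56.1% of pSOL1 probes over its 4 scans were above the 95th percentile of negative controls, a level that 5% of the controls pass. As the main part of the signal, such a floor stays open for most probes at 0.5 to 3.0 µg. There 19.8% to 22.1% were above that level over 6 scans, and no biological explanation was tested.

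The pSOL1 median ranged over 0.58 (log2) between the 4 scans of the slide with 5.0 µg. Saturated pSOL1 probes are argued against, since only 2 of 178 genes had one, and these could add at most 0.10 (0.096) to the range wherever they lay. The offset of 50 added to dim signals is a candidate explanation, as the range was 0.18 (0.175) with the software's signals, which differ in background and dye steps as well. All 4 scans held the same hybridized material, so a biological difference has no place here.

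Unadjusted p values under 0.05 for a trend with amount made up 25.4% of genes. Ratios drawn toward 0 by the offset are argued against as the whole cause, with 22.4% under the software's signals, although 73.9% of such genes had a slope and a ratio of one sign. Saturated probes are argued against, with 26.1% when such spots were left out. A slide that differs for another reason cannot be told apart from the amount, because each amount was 1 slide. Leaving out 1 array gave 11.5% (0.5 µg), 18.0% (1.0 µg), 28.5% (3.0 µg) and 15.7% (5.0 µg). Such fits have fewer residual degrees of freedom, so a lower share does not single out a slide. The design gives no biological explanation, as the pools were the same.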

How the results depend on the processing

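The alternatives here were chosen before the data were examined, except 2 additions to the iron uptake list, 1 gene left out of each of 2 lists, and lists moved along the chromosome, all chosen after. None of the named genes at least 2-fold apart changed direction under any of them, and 50 to 54 of the 72 named genes were at least 2-fold apart. Many of these genes were named for the size of their ratios. Leaving out or reweighting arrays could not reverse a ratio with one sign on all 10 arrays, so only settings that changed the values themselves could do so. The 11 lists that stood apart, the pSOL1 lists among them, did so under every setting of background, normalization, probe summary and arrays. They were joined by pyruvate and hydrogen without saturated spots and by iron uptake with the mean of the probes or with CAC1031 added (12 lists). Histidine synthesis without CAC0935 (−0.60) and phage genes without CAC0313 (−0.73) still stood apart, but with lists moved along the chromosome histidine synthesis and sugar uptake did not and iron uptake did (10 lists). Leaving out an array or amount gave 394 to 420 genes higher in M5, 238 to 258 higher in ATCC 824, 636 to 678 in all and a pSOL1 median of −1.65 to −1.44. Counted once per setting, 61 list medians and 181 values of named genes moved by more than their SD over amounts, against 493 and 1546 that did not. These counts include the settings that left out an array or amount, which share most arrays with the main values and so could move little. The software's signals gave 617 genes higher in M5, 330 higher in ATCC 824 and a pSOL1 median of −3.87, and the series table a median of −3.03, and which of their steps was the cause was not tested. An offset of 16 gave −2.10 (−2.095), a change of that step alone. By construction, a 1.5-fold limit gave 1294 genes (755 higher in M5, 539 higher in ATCC 824) and a 3-fold limit 246 (151 and 95).

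Genes with a trend numbered 0 with limma (982 at an unadjusted p under 0.05), 20 with median centring, 3 with the software's signals, 1962 with 10 arrays and PMT covariates, and 0 to 116 with 1 array left out (11 without 1.0 µg, 116 without 3.0 µg), and the cause was not tested. It was also 0 without saturated spots (991), without the filter on dim probes (985) and with a robust trended prior (1036). Signal over background limits the ratios of pSOL1 genes. At PMT 80 and 40 the median M5 signal of their probes was 9.5 beside 7.9 at negative controls at 0.5 µg, and 110.1 beside 58.3 at 5.0 µg. With a limit of 2.6 SDs above local background, shares of probes in Cy3 and Cy5 were 99.995% and 97.232% at 0.5 µg, 99.991% and 97.827% at 1.0 µg, 100.0% and 99.977% at 3.0 µg, and 100.0% and 100.0% at 5.0 µg. At PMT 60 and 20 they were 94.557% and 92.631% at 0.5 µg and 98.102% and 96.823% at 3.0 µg by the software's mark. Probes with more than 0 saturated pixels, a wider definition, made up 0.0512% in Cy3 and 0.1303% in Cy5 at 0.5 µg and PMT 60 and 20, and 0.5071% in Cy5 at 80 and 40. At 1.0 µg they made up 0.335% in Cy5 at 80 and 20 and 1.6562% at 80 and 40. At 3.0 µg they made up 0.2698% and 0.7816% at 60 and 20, and 0.4885% and 2.0237% at 80 and 40. At 5.0 µg they made up 1.1398% and 7.8763% at 100 and 100, 0.4094% and 0.3908% at 60 and 10, 0.7444% and 0.3954% at 80 and 10, and 0.7769% and 3.3124% at 80 and 40.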

Other observations

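The groups and genes in this part were chosen after their values were seen, as were the counts of neighbouring loci. The longest run of neighbouring loci at least 2-fold the same way was CAC1988 to CAC2018, 31 loci higher in M5 with a median of 1.96 (1.08 to 2.98), which holds CAC2004 at 1.67 ± 0.13 (n = 4 amounts). Runs higher in M5 also covered 10 loci from CAC1798 to CAC1807 (median 1.70), with nusA (CAC1799) and infB (CAC1802), and 9 loci from CAC3624 to CAC3632 (median 2.09), with oppF (CAC3628) to oppA (CAC3632). Others were 9 loci from CAC1365 to CAC1373 (median 1.41), with cbiM (CAC1365) and cobT (CAC1372), 7 loci from CAC0892 to CAC0898 (median 1.99), with aroB (CAC0894) and aroK (CAC0898), and 6 loci from CAC0105 to CAC0110 (median 1.46), with cysD (CAC0109) and cysN (CAC0110).

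Runs lower in M5 included 6 loci from CAC0590 to CAC0595 with a median of −2.57, 4 of them with a gene name, ribA at −2.79 ± 0.32, ribH at −2.73 ± 0.27, ribD at −2.59 ± 0.36 and ribB at −2.55 ± 0.25. The 5 loci CAC1029 to CAC1033 had a median of −2.28, with feoB (CAC1031) at −2.55 ± 0.57. Loci from CAC1885 to CAC1900 (16 loci, median −1.42) and from CAC1875 to CAC1883 (9 loci, median −1.80) were lower, as were 5 loci from CAC2777 to CAC2781 (median −1.76). Single genes included serA (CAC0015) at 3.69 ± 0.18, luxC (CAC2287) at 3.49 ± 0.14, thioredoxin reductase (trxB, CAC1548) at −2.14 ± 0.19 and thioredoxin (trxA, CAC1547) at −1.88 ± 0.26.

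Over the chromosome, 29 runs of at least 5 neighbouring loci, 21 higher and 8 lower in M5 with 220 loci in all, were at least 2-fold the same way, against at most 1 in 1000 permutations of the loci. Ratios of neighbouring loci correlated at r = 0.612 over 3697 pairs, where the highest of 10000 permutations was 0.064. Probes in neighbouring spots of the array correlated at r = −0.005 over 20344 pairs, so position on the slide did not give such a relation. Loci are not independent replicates, and neighbours were taken from locus numbers, with no coordinates used here.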
